A study of Mus musculus with 2 samples.

How the data were processed

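Smyd2, a lysine methyltransferase, was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in mouse renal epithelial cells of embryonic origin, called MEK cells. One library came from cells wild type for Pkd1, the gene mutated in most families with dominant polycystic kidney disease, and 1 came from Pkd1 null cells. Per the labels' protocols, both were precipitated from sonicated nuclei with the same lot of a Smyd2 antibody. No input, control-antibody or Smyd2-deficient library was analysed here, so no background measured in the same way stands beside the values.

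The authors deposited 1 list of genomic regions per library. Per the file headers, each row gives a chromosome, start, end, a nearby gene with its orientation and distance where one was found (at most 1947 bp away), and 1 value taken from that library's mapped reads. The deposited value is on a log2 scale: 2 raised to the value gave a whole number for each of the 187 wild-type and 235 null regions, within a relative tolerance of 0.001, with a lowest number of 11 in both lists. It was therefore read as the log2 of a read number that the authors did not scale to library depth. The genome build was GRCm38, per the submitters' processing notes. The aligner, the rule that chose the regions, its threshold and any use of a control are not given in the sources used here. Region widths were multiples of 150 bp. Total sequencing depth per library is unknown, because the lists hold only the reads inside listed regions (7474 in the wild-type list and 6718 in the null list).

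Genes came from a RefSeq gene table of the same assembly (GRCm38.p6), with 49943 genes on chromosomes 1 to 19, X and Y. As a check of the build, 77 of 79 wild-type regions and 111 of 113 null regions that the authors' lists place over a gene with a symbol in the table overlapped that gene's span. The table gives spans without strand, exons or sequence. The planned share of regions at transcription start sites was therefore replaced by the share with a midpoint within 1 kb of either end of a gene, for observed and random regions alike. Exon, intron and UTR positions, GC content and repeats were not analysed here.

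Regions were called shared when they overlapped by at least 1 bp. Each list was compared with 1000 random placements that kept every region's width and chromosome and drew its position uniformly over the span of annotated genes. Assembly gaps and poorly mappable sequence were not masked. A placement p is 1 plus the number of placements that reached the observed count, divided by the number of placements plus 1, so 0.000999 is the smallest it can be. It is one-sided and describes positions in 1 list, not replicate error. Shares carry 95% Wilson intervals, except that a count of 0 carries the limit of 3 counts over the total, and ratios of reads carry exact 95% binomial intervals. Both cover counting error only. Reads at shared regions were tested for a single ratio with a Monte Carlo chi-square and for each region with an exact binomial test against the ratio of the other shared regions, with Benjamini-Hochberg adjustment. Shares were compared between the lists with Fisher's exact test, two-sided. The 31 shared regions counted in both lists there, and the test took no account of that pairing. All of these tests compare 2 libraries or 2 lists. With 1 library per genotype there is no replicate error, so no test of the genotypes was made.

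In all, 15 gene lists were fixed before the data were examined, of which 12 were pathway or cell-type lists holding 528 genes of the table. In the pattern list for histone, ribosomal protein and small RNA genes, names beginning with H2- (histocompatibility genes) were removed. A gene counted as hit when it covered a region's midpoint or, where no gene did, when it was the nearest gene within 50 kb. The rules for naming genes were fixed at the same time as the lists. They took the 8 shared regions with most reads in the wild-type library, the 8 single-list regions with most reads in each list, and every pathway or marker gene with a region inside it or within 5 kb (at most 25 per list). Pkd1 and Smyd2 were always named. Predicted genes and pseudogenes were given by position. Alternatives covered the overlap rule, read thresholds, window sizes, gene classes and placements within 1 Mb. The ratio of reads at shared regions, the share inside genes, gene length and the counts per chromosome were added after the data were seen.

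Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. On simulated data, all 50 planted overlaps were found. After 40 of 200 simulated regions were moved to gene ends, the count there went from 11 to 49. Of 30 uniformly placed lists, 0 were called as enriched inside genes. In 100 simulated sets of 17 shared regions with 3 regions changed 2-fold, 73.7% of changed regions and 2.21% of unchanged regions were called. These sets took the depth of the 17 shared regions with most wild-type reads and adjusted over 17 regions. The reported test adjusted over 31 regions, and the share called among those with fewer reads was not simulated.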

Results

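Smyd2 ChIP-seq regions were listed for 1 Pkd1 wild-type and 1 Pkd1 null library of mouse renal epithelial cells, to find genes that Smyd2 occupies in each cell type. The wild-type list held 187 regions covering 144.9 kb and the null list 235 regions covering 183 kb, with a median width of 750 bp in both. Most regions held few reads: the median was 14 reads (quartiles 12 and 17) in the wild-type list and 13 reads (quartiles 12 and 16) in the null list. Regions of 20 reads or fewer made up 84.5% of the wild-type list and 89.4% of the null list. By contrast, the 4 regions with most reads held 54.0% of the 7474 listed wild-type reads and 43.5% of the 6718 listed null reads. Each genotype had 1 library, so the values below have no replicate error, and intervals cover counting error only.

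The first comparison asked which regions were listed in both cell types. In all, 31 regions were shared, and the regions with many reads were nearly all among them. Chl1, a neural cell adhesion gene, Cdk5rap2, which encodes a centrosomal protein, Ank1, which encodes a membrane-skeleton ankyrin, and Acacb, an acetyl-CoA carboxylase gene, each held a region in both lists, the last 3 being picked after their values were seen. The shared regions made up 16.6% of the wild-type list (Wilson 95% interval 11.9 to 22.6) and 13.2% of the null list (9.45 to 18.1). All 18 wild-type regions of 30 or more reads were shared (interval 82.4 to 100%), against 13 of 169 with fewer reads (7.69%, interval 4.55 to 12.7). In the null list 13 of 14 regions of 30 or more reads were shared (92.9%, interval 68.5 to 98.7), against 18 of 221 with fewer (8.14%, interval 5.21 to 12.5). Random placements of the wild-type regions gave a mean of 0.022 shared regions, and none of 1000 reached 31 (one-sided placement p of 0.000999, the smallest that 1000 placements can give). The placements did not mask poorly mappable sequence, and no input library was analysed. This p therefore cannot tell Smyd2 occupancy from background common to both libraries.

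**Figure D1:**
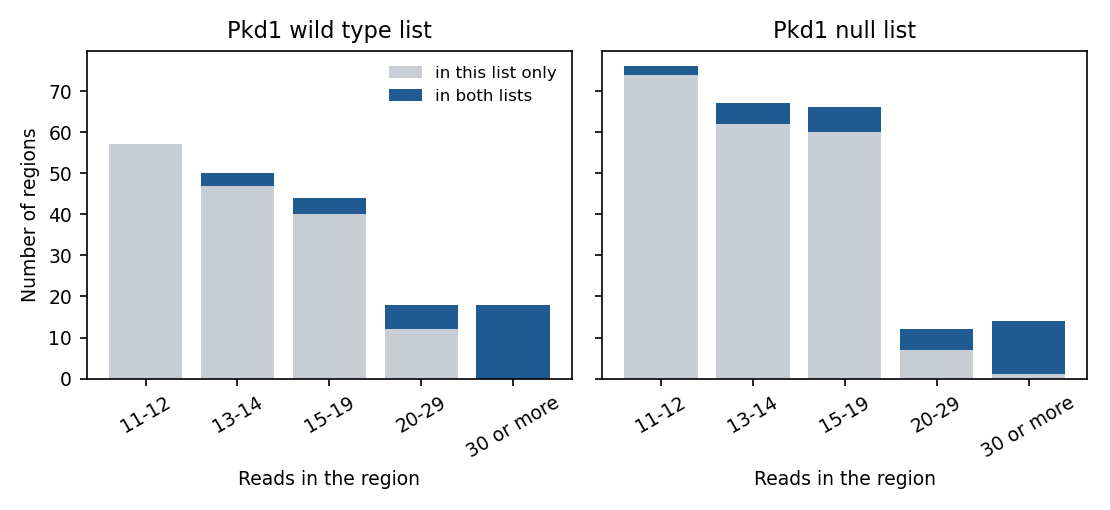
Number of listed regions (vertical axis) by reads in the region (horizontal axis) in the Pkd1 wild-type and Pkd1 null lists, with 1 library each; dark bars are regions in both lists and light bars regions in 1 list only. All 18 wild-type regions and 13 of 14 null regions of 30 or more reads lay in both lists, against 0 of 57 wild-type and 2 of 76 null regions of 11 or 12 reads.

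The 4 shared regions with most reads lay on chromosomes 2 and 9 (GRCm38). The region at chromosome 2, 98665801 to 98667750, held 1893 wild-type and 1396 null reads, and its neighbour at 98661751 to 98664450 held 1284 and 902. On chromosome 9, the region at 35304751 to 35305950 held 593 and 427 reads, and the region starting at 3021751 in the wild-type list held 267 and 198. The authors' list assigns both chromosome 2 regions and the latter chromosome 9 region to predicted genes, and the former chromosome 9 region lay inside a long non-coding RNA gene of the gene table. The next 4 were at chromosome 4, 3089251 to 3091350 (109 and 65 reads), chromosome 12, 74803501 to 74805000 (108 and 82 reads) and 3109501 to 3110550 (107 and 68 reads), and inside Chl1 at chromosome 6, 103648651 to 103649700 (95 and 58 reads). Chl1 spans 103510584 to 103733038 in the gene table and was the only protein-coding gene among these 8 regions. Over all 31 shared regions, 12 lay inside protein-coding genes. The remaining members, named after their values were seen, were Cdk5rap2 with 67 wild-type and 39 null reads, Mdga2 with 60 and 44, Ank1 with 53 and 37, Cdh23 with 52 and 27, Acacb with 45 and 32, a predicted gene at chromosome 13, 77438551 to 77439450, with 34 and 19, Lamc3 with 24 and 12, Mamdc2 with 20 and 18, Pde1c with 19 and 14, Ndst4 with 17 and 17, and Litaf with 15 and 14. None of the 31 had its midpoint within 1 kb of a gene end, and a count of 0 allows a share of up to 9.68% (3 counts of 31, in place of a Wilson interval).

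The second comparison asked whether reads at shared regions differed between the libraries. Wild-type reads were higher at 28 of the 31 regions, including Chl1, Cdk5rap2 and Cdh23, and summed to 1.41 times the null reads (5259 against 3726, exact 95% interval 1.35 to 1.47). Over the 22 regions with identical coordinates in both lists the ratio was also 1.41 (interval 1.35 to 1.47). The ratio was 1.36 (interval 1.26 to 1.45) at the chromosome 2 region with most reads, 1.64 (1.17 to 2.31) at Chl1 and 1.72 (1.14 to 2.62) at Cdk5rap2. A single ratio was not rejected over the 31 regions (Monte Carlo chi-square, p = 0.252), nor over the 17 with 60 or more reads in both libraries together (p = 0.168). At chromosome 9, 24541651 to 24542550, the ratio was highest, 2.78 (75 against 27 reads, interval 1.77 to 4.49). Its exact binomial p against the other shared regions was 0.00175, or 0.0543 after Benjamini-Hochberg adjustment over 31 regions. The lowest ratio, 0.565 (13 against 23 reads, interval 0.263 to 1.16), was at chromosome 13, 86305651 to 86306400, with an adjusted p of 0.156 in the same exact test. Because total depth is unknown, the overall ratio of 1.41 cannot be divided into depth and occupancy, and reads were compared between 2 libraries rather than 2 genotypes.

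**Figure D2:**
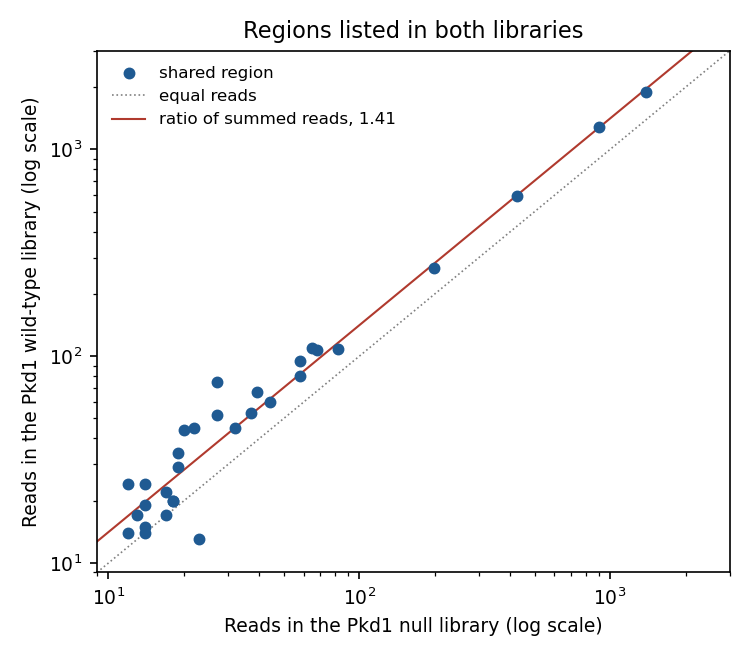
Reads in the Pkd1 null library (horizontal axis, log scale) and the Pkd1 wild-type library (vertical axis, log scale) at the 31 shared regions, 1 point per region; the dotted line marks equal reads and the solid line the ratio of summed reads, 1.41. Points lie above the dotted line for 28 of 31 regions.

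The third comparison concerned regions in 1 list only, 156 in the wild-type list and 204 in the null list. Their median was 14 reads in wild type and 13 in null. Among wild-type regions, the highest was at chromosome 6, 127523551 to 127524150, with 28 reads, 9.62 kb from the nearer end of Parp11. It was followed by regions inside Arhgap15, which encodes a Rac GTPase-activating protein (chromosome 2, 44066101 to 44066850, 25 reads), Plekhg1 (23 reads) and Slc22a22 (22 reads). Regions inside Prkdc, which encodes the catalytic subunit of DNA-dependent protein kinase, Lrrc8c, a subunit gene of volume-regulated anion channels, and Ano2, a calcium-activated chloride channel gene, held 21 reads each. A region inside Spag17 held 20 reads.

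In the null list, the highest single-list region was at chromosome 9, 3034801 to 3036900, with 150 reads, and the next held 28 reads. For that next region, at chromosome 8, 18930751 to 18931650, the authors' list names Xkr5 at a distance of 1079 bp with the orientation upstream. Whether that label places the gene or the region upstream is not stated in the sources used here. The region lay inside the longer Xkr5 span of the gene table. Further null-list regions lay inside Rbfox3, which encodes a neuronal splicing factor (chromosome 11, 118641001 to 118641900, 24 reads), Gnao1, a G protein alpha subunit gene (chromosome 8, 93928501 to 93929250, 23 reads), and Wipf1, an actin regulator gene (chromosome 2, 73522051 to 73522800, 21 reads). Outside protein-coding genes were regions at chromosome 14, 104336551 (25 reads), chromosome X, 103636951 (23 reads) and chromosome 16, 61636651 (21 reads). The lists do not give reads for a region in the library where it was not listed, so absence from a list shows only that the region was not listed there, not that the libraries differed.

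The fourth comparison asked where the regions lay relative to genes. In both lists regions lay inside genes more often than random placements did: 107 of 187 in wild type (57.2%, interval 50.1 to 64.1, random mean 48.3%) and 144 of 235 in null (61.3%, interval 54.9 to 67.3, random mean 48.3%). The placement p was 0.00999 in wild type and 0.000999 in null. Single-list regions carried the excess, with 92 inside genes in wild type (random mean 75.2) and 129 in null (random mean 98.6). Of the 31 shared regions, 15 lay inside genes, against random means of 15.1 in wild type and 15 in null. Protein-coding genes held 94 wild-type and 119 null regions, against random means of 74.9 and 94.5. Among the regions with most reads, 60.2% of 93 lay inside genes in wild type (placement p of 0.015) and 52.1% of 117 in null (placement p of 0.247). The share inside genes over the whole lists did not differ between them by Fisher's exact test (p = 0.425), which compares the lists and not the genotypes.

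Near gene ends, the null list exceeded its random placements within 1 kb and the wild-type list did not, although within 500 bp its 12 regions lay at the upper bound of the central 95% (2 to 12), and the share within 1 kb did not differ between the lists by Fisher's exact test. Within 1 kb of a gene end lay 24 null regions (10.2%, interval 6.96 to 14.7, random mean 6.24%, placement p of 0.014) and 14 wild-type regions (7.49%, interval 4.51 to 12.2, random mean 6.37%, placement p of 0.304), with Fisher's exact p = 0.393 between the lists. For protein-coding genes the counts were 16 of 235 in null (random mean 7.11, placement p of 0.003) and 6 of 187 in wild type (random mean 5.9, placement p of 0.529). Fisher's exact p between the lists was 0.124. Within 500 bp of any gene end the null list held 17 regions (random mean 7.89, placement p of 0.000999). None of the 31 shared regions had its midpoint within 1 kb of a gene end, so every region in these counts was in 1 list only. The protein-coding genes in these counts were named after their values were seen. In the wild-type list they were Gata6, which encodes a zinc finger transcription factor (16 reads), Socs5, a suppressor of cytokine signalling (11 reads), Hjurp, a centromere histone chaperone gene (16 reads), Ttll13 (14 reads), Camk2n2 (14 reads) and Ctnnb1 (12 reads). In the null list the 16 included Mxi1, which encodes a MAX-binding repressor (18 reads), Slc14a1, a urea transporter gene (14 reads), Rnd3 (13 reads), Rtf1 (13 reads) and Rbbp4, which encodes a histone-binding protein (13 reads). The strand of these genes was not used, so start and finish of a gene were not told apart. Among the 117 null regions with most reads the share was 6.84%, with a placement p of 0.429.

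**Figure D3:**
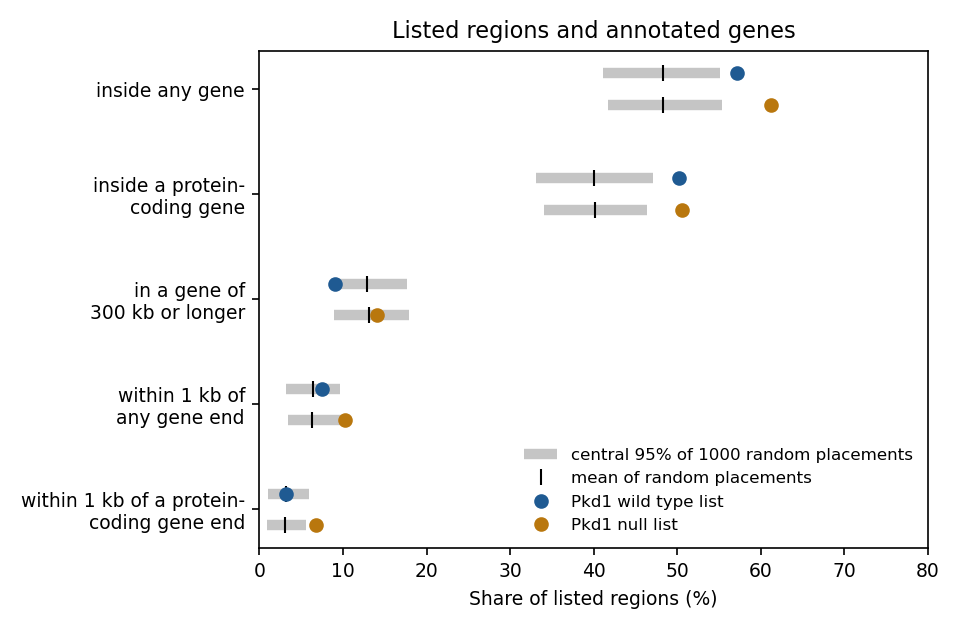
Share of listed regions (horizontal axis, percent) in 5 positions relative to annotated genes (vertical axis), for the wild-type and null lists; points are observed shares, grey bars the central 95% and black ticks the mean of 1000 random placements. Regions inside genes were 57.2% in wild type and 61.3% in null, against a random mean of 48.3% in each.

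The final comparison asked whether genes of renal, cystic disease or signalling pathways held regions. No list was hit more often than random placements after adjustment over 30 list and library combinations (lowest placement p of 0.107, lowest Benjamini-Hochberg adjusted p of 1). In the null list, 2 of 54 polycystin and cilium genes were hit, Pkhd1, the gene of recessive polycystic kidney disease, and Ahi1, a cilium transition zone gene, against a random mean of 0.541. The Pkhd1 region at chromosome 1, 20571001 to 20571750, held 18 reads and lay 46.7 kb from the nearer gene end, and the Ahi1 region at chromosome 10, 21025201 to 21025800, held 13 reads. Single hits in the null list were Il6ra, an interleukin-6 receptor gene, with 13 reads, Lef1, a Wnt-pathway transcription factor gene, with 14 reads, Setdb2, a lysine methyltransferase gene, with 12 reads, and Akt2, a kinase gene, with 14 reads in a region whose midpoint lay 2749 bp from the gene. In the wild-type list, the hits were Ctnnb1, the beta-catenin gene, and Pde4d, a cAMP phosphodiesterase gene, with 11 reads. The Ctnnb1 region, at chromosome 9, 120932401 to 120933000, held 12 reads. Its midpoint lay 700 bp from the Ctnnb1 span of the gene table, whereas the authors' list gives the region as overlapping Ctnnb1. None of these 8 regions was shared.

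Over the 12 pathway and cell-type lists together, 2 of 528 genes were hit in wild type (random mean 3.26, central 95% 0 to 7) and 6 in null (random mean 4.08, central 95% 1 to 9). The lists of cell cycle, apoptosis, TGF-beta and matrix, Hippo and junction, kidney segment, fibroblast, and endothelial and immune genes had 0 hits in both libraries. Their random means were only 0.117 to 0.427 hits, and most placements also gave 0, so these zeros do not show avoidance of such genes. Olfactory and vomeronasal receptor genes had 3 hits in wild type and 5 in null, against random means of 3.73 and 4.35. Histone, ribosomal protein and small RNA genes had 2 and 5 hits (random means 4.36 and 5.26), and zinc finger genes 1 and 1 (random means 1.65 and 2.09), the latter being Zbtb16 in both lists. The 5 null-list hits included Rps6kc1, a kinase gene caught by the name pattern. Pkd1 itself, at chromosome 17, 24548689 to 24596514, had no listed region nearer than 443 kb in wild type, and the nearest null region was 13952 kb away. Smyd2, at chromosome 1, 189880492 to 189922495, had its nearest region 30014 kb away in wild type and 914 kb away in null.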

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

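Alternatives on the read ratio, on regions inside genes, on gene length and without regions of 30 or more reads, and placements within 1 Mb for gene positions, were chosen only after the result was seen. No paired analysis was possible because each genotype had 1 library, and for the same reason no library could be left out. Of 54 values under alternative settings, 41 kept their direction and their side of a placement p of 0.05, or, for counts and the read ratio, stayed close to the value reported (counts within 1.5 times). Part of that tally was fixed by the settings. Placements within 1 Mb cannot change the 31 shared regions, and leaving out chromosome Y took only 187 wild-type regions to 186. Values past no threshold under either setting also counted as kept. Restricting each list to its regions with most reads left 93 wild-type and 117 null regions. Gene list hits over 12 lists were then 0 in wild type and 3 in null, the null share within 1 kb of a gene end was 6.84% (placement p of 0.429) and the null share inside genes was 52.1% (placement p of 0.247). Fewer regions were tested there, and the random means hardly moved (6.16% and 48.4%). At or above the median reads of both lists together (14 reads), the wild-type list held 109 regions and the null list 114. A 500 bp window took the wild-type gene-end share past the threshold (6.42%, random mean 3.42%, one-sided placement p of 0.031, at the upper bound of the central 95%), and a 5 kb window took the null share below it (28.1%, random mean 23.5%, placement p of 0.0639); the cause was not tested. The wild-type share in long genes, below its random mean for genes of 300 kb or longer (9.09% against 12.9%), lay above it for genes of 100 kb or longer (26.2% against 25.9%), past no threshold either way. Shared regions numbered 31 or 32 under other overlap rules, 27 among those 93 and 117 regions and 29 with equal numbers, but 13 without regions of 30 or more reads. The ratio of reads at shared regions was 1.52 without the 4 regions with most reads. Summits, sequence-based shares and feature priorities were planned and not run, because the lists give no summit and no sequence or exon annotation was used.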

Other observations

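The tests of a single read ratio, chromosome starts, equal read rates, chromosome counts and the null-list region of 150 reads were chosen only after the result was seen, and the tests of gene density, long genes and low-read regions were chosen after the excess inside genes was seen but before their own results were. Long genes, named here after their values were seen, held regions in both lists, among them Lrp1b with 20 reads, Cntnap2 with 14 reads and Mdga2 with 60 reads in the wild-type list, and Dlg2 with 12 reads, Robo2 with 17 reads, Wwox with 18 reads and Fhit with 14 reads in the null list. Genes of 300 kb or longer held 17 wild-type regions (random mean 24.2, central 95% 16 to 33) and 33 null regions (random mean 30.7, central 95% 21 to 42), so neither list exceeded random placements. Away from shared regions, 3 protein-coding genes held a region of each list at different positions: Zbtb16, which encodes a transcriptional repressor (14 and 13 reads), Cacng3, a channel subunit gene (15 and 13 reads), and Prpsap1 (16 and 14 reads). Random placements gave a mean of 1.45 such genes (central 95% 0 to 4), which is consistent with chance from gene length alone.

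Chromosome 17 held 12 wild-type and 4 null regions (Fisher's exact p = 0.0184, adjusted p = 0.386 over 21 chromosomes). Against annotated chromosome length, the null list departed from proportion (Monte Carlo chi-square, p = 0.0211) and the wild-type list gave p = 0.536. That comparison gave chromosomes X and Y their full spans of 171 and 90.8 Mb. They held 8 and 0 null regions and 6 and 1 wild-type regions. No test without them was run, so the departure may rest on the sex chromosomes. The null-list region on chromosome 9 with 150 reads would hold 213 wild-type reads (Poisson 95% range 185 to 242) at the ratio of 1.42 seen over shared regions of 60 or more reads. Starting at 3034801, it lay near the shared region at 3021751 to 3024000 of the wild-type list, and both lay within 500 kb of the first 3 Mb. The region of 150 reads was not in the wild-type list, but how regions were chosen is not given in the sources used here, so its absence is not evidence of fewer wild-type reads.

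Regions with many reads were mostly shared, and a single ratio of their reads between the libraries was not rejected. A single factor of depth was not excluded by that test (Monte Carlo chi-square over 17 regions, p = 0.168). The ratio was 1.38 (exact 95% interval 1.32 to 1.45) over the 4 regions with most reads. Over the other 27 shared regions it was 1.52 (1.39 to 1.67), and these ratios were not tested against each other. Sequence next to the unassembled start of mouse chromosomes may account for the 3 shared regions within 500 kb of the first 3 Mb (3 of 31 shared against 0 of 156 wild-type single-list regions, Fisher's exact p = 0.00419, and against 2 of 204 null single-list regions, Fisher's exact p = 0.0174), but 28 shared regions lay elsewhere. Those 28 included the 3 regions with most reads (1893, 1284 and 593 in wild type). The values argue against binding within 1 kb of gene ends as the source of most shared regions. There, 0 of 31 had their midpoint, which allows a share of up to 9.68%. Depletion at gene ends could not be told, because the central 95% of random placements was 0 to 5 regions. Collapsed repeats elsewhere, and Smyd2 occupancy away from gene ends, stay untested without sequence or an input library.

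Regions in 1 list only had medians of 14 wild-type and 13 null reads against a lowest listed count of 11, the null-list region of 150 reads being far above the rest. If each had the same read rate in both libraries apart from the ratio of 1.42 (wild type over null) and were listed at 11 reads or more, 71.9 wild-type regions under 30 reads would be expected in the null list (central 95% 61 to 83) and 215 null regions in the wild-type list (210 to 219), against 13 and 18 observed. A limit of 20 reads, which listed regions of 11 to 19 reads rule out as a uniform limit, would give 4.27 (1 to 8) and 110 (98 to 123), so the size and, for wild type, the direction of the gap depend on a listing rule that is not given in the sources used here. Equal read rates under an unknown listing rule, read rates below the listed counts in regions picked for their height, and a difference between the genotypes stay open because there was 1 library of each.

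Placements within 1 Mb argued against gene density as the whole cause of the excess inside genes in the null list, where 0 of 1000 reached the count, and less clearly in wild type, where 28 of 1000 did and the count of 107 lay at the upper bound of the central 95% (83 to 107). Long genes did not take the excess either: genes under 300 kb held 90 wild-type regions (random mean 66.1) and 111 null regions (random mean 82.9), against 17 and 33 in longer genes. Without regions of 30 or more reads, 98 wild-type and 138 null regions lay inside genes, above central 95% ranges of 69 to 94 and 92 to 122 on the same chromosome, but the wild-type 98 lay within 75 to 99 for placements within 1 Mb, and among the regions with most reads the share was 60.2% of 93 in wild type (random mean 48.9%) and 52.1% of 117 in null (random mean 48.4%). Easier mapping of gene sequence and open chromatin in the sonicated material may contribute and were not tested. Smyd2 occupancy of gene bodies was not tested either, because no input or Smyd2-deficient library was analysed, and stays a hypothesis. The 31 regions listed in both libraries showed no excess inside genes (15, wild-type random mean 15.1, central 95% 10 to 20).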
